A study of Mus musculus with 8 samples.

How the data were processed

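Total RNA was measured in 8 mouse libraries, 1 from frozen and 1 from FFPE tissue of each of 4 organs. RNA was extracted with Trizol, after deparaffinisation for FFPE tissue, and sheared in a PIXUL sonicator, per the labels' protocols. HISAT2, featureCounts and limma are named, without versions or settings, in the submitters' processing notes, together with genome mm10. The annotation, the strand setting, the scaling method and the read length are not given in the sources used here.

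The authors deposited 1 table of log2 values for 27179 genes, of which 1275 have no symbol and 25271 (93.0%) matched a gene of the reference annotation. Its values are log2 counts per 1e+06 reads (CPM) with 0.5 added to each count, on an effective library size that is the total times a scaling factor of 0.500 to 1.76, as worked out from the deposited values themselves. Each column then gave whole reads for 100% of its values, within 1e-06 of a whole number. The recovered totals were 10180972 to 20526813 reads per library. At these totals 3 reads, the floor used for genes without reads, stand for 0.119 CPM in frozen brain and 0.292 CPM in frozen heart. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Filtering of reads before counting is not given in the sources used here.

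Libraries were grouped by the tissue and treatment labels. Each group holds 1 library, and the labels do not say how many animals gave a sample or whether tissue was pooled. FFPE was compared with frozen tissue within organs. The p-values of that comparison rest on how the difference varies between these 4 organs, with each gene's spread drawn toward a trend over all genes. Printed SEs come from that drawn spread. For Xist the 4 organ differences had an SD of 5.92 beside a printed SE of 1.78, and for Cyp2d9 0.24 beside 0.25. Whether the organs came from different animals is not given, so they may not be independent. The p-values of an organ against the others rest on the 2 libraries per organ, with spread drawn in the same way. The model, fitted with limma 3.58.1 in R 4.3.3 with a mean-variance trend, had a term for each organ and 1 for preservation, with 3 residual degrees of freedom and a prior of 5.35. Genes above 1 CPM (log2 CPM above 0) in at least 2 libraries entered, which left 15819. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are on the scale with 0.5 reads added, which can understate or create changes of genes with few reads. With 0 reads in both libraries the difference was 0.49 in brain and −0.36, −0.37 and −0.48 in heart, kidney and liver. A single FFPE read against 0 gave 2.08 in brain.

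Gene lists (54, with 52 of at least 3 tested members) were fixed before the data were examined from textbook knowledge of the tissues, of RNA classes and of stress responses, with 40 pairs of organ and list (38 tested) for the organ comparisons. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with limma's fry, adjusted over the lists. With an estimated correlation camera also rests on the 3 residual degrees of freedom, which makes a call harder to reach for any list. In liver the bile acid and cytochrome P450 list had an estimated correlation of −0.03. Its unadjusted p still went from 6.54e-15 to 0.00333 (limma's camera, preset and estimated correlation). A call lost there therefore does not show that members vary together, and neither form settles a call. Per organ, a list's median difference was also placed among 10000 random lists of the same size matched on mean expression. The rule for named genes was fixed beforehand too. It took the 12 largest rises and 12 largest falls among called genes with a symbol and the same sign in 4 of 4 organs, the 6 largest differences per organ among genes higher there than in all other organs in both preparations, up to 4 members per list with the largest absolute change, called members first, and 5 sex-linked genes. Genes named outside this rule were chosen after their values were seen, and are named so where they occur. Organ-enriched genes were those above 1 CPM and 3 log2 units (8-fold) above every other organ.

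The fit and the list test were tested on simulated data with the 15819 genes. Of 100 genes changed by 1 log2 unit between FFPE and frozen tissue 42% were called, and of 100 changed by 2 log2 units 71%, with 8 false calls (6.61% of all calls). For brain against the other organs the shares were 41% and 73% with 14 false calls (10.9%). Of 20 random lists without a change 0 were called in the simulated FFPE comparison. Noise was drawn independently for each gene there. That result therefore cannot show how the preset correlation performs on lists whose members vary together.

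Alternatives set beforehand were no filter, a stricter filter, quantile normalization, median centring, no mean-variance trend, robust variance, log2(CPM + 5), limma's voom on the recovered reads, leaving out each library, a 2-fold minimum and models without organ or preservation term. Removal of trends with transcript length and GC content, protein-coding genes only, removal of sex-linked genes with the sex-biased liver lists, and removal of the brain pair were added after seeing the data. Lengths and GC content came from GENCODE basic transcripts of the mouse, as the median over a gene's transcripts, and covered 14559 of the 15819 genes, 441 of the 535 called genes and 160 of 165 ribosomal and oxidative phosphorylation members. Coordinates are those of RefSeq on the GRCm38 assembly, the mm10 build. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Assays of the same toolbox other than RNA sequencing were not analysed here.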

Results

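Total RNA from mouse brain, heart, kidney and liver was sequenced after 2 ways of keeping the organ. For each of the 4 organs there was 1 library from flash-frozen tissue and 1 from tissue that had been fixed in formalin and embedded in paraffin (FFPE), the form in which pathology archives keep tissue, which gave 8 libraries. FFPE processing crosslinks and fragments RNA. The series was made for a toolbox that profiles frozen and FFPE tissue with several assays, and its design text names correlation, differential expression and principal components as the comparisons made. The questions followed here were whether an FFPE library kept the profile of its organ, which genes marked each organ in both preparations, and which genes differed between FFPE and frozen tissue. Reads assigned to genes numbered 10180972 (FFPE brain) to 20526813 (frozen heart) per library. Genes with at least 1 read numbered 18722, 16098, 17129 and 15493 in frozen brain, heart, kidney and liver, and 21002, 18140, 20349 and 16725 in the FFPE libraries of the same organs.

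Ribosomal RNA took a large part of the reads. Mitochondrial ribosomal RNA, the rRNA of the mitochondrion's own ribosomes, held between 26.8% of reads in FFPE brain and 55.6% in frozen heart. The nuclear 45S precursor and 18S rRNA together held 12.8, 15.7, 26.1 and 21.6% of reads in frozen brain, heart, kidney and liver, and 2.92, 11.3, 1.49 and 2.67% in FFPE. Malat1, a nuclear long non-coding RNA, held 1.36, 0.561, 1.25 and 0.511% of reads in the frozen libraries and 2.89, 1.50, 4.74 and 1.53% in FFPE. Messenger RNAs encoded by the mitochondrial genome held 1.39, 3.66, 2.38 and 1.86% in frozen and 1.94, 6.06, 5.85 and 4.76% in FFPE. The 95% exact binomial (Clopper-Pearson) intervals of these shares reached at most 0.0273 percentage points to either side and cover counting error only.

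The 2 libraries of an organ resembled each other more than any library of another organ. Across the 15819 genes above the level filter, the log2 values of frozen and FFPE libraries correlated at Pearson r = 0.950 for brain, 0.955 for heart, 0.959 for kidney and 0.970 for liver, while the highest r between different organs was 0.705. These correlations run across genes, which are not independent replicates. The first 3 principal components held 53.9, 22.3 and 18.4% of the variance and separated the organs. The fourth held 2.24% and separated the 4 frozen from the 4 FFPE libraries. Within an organ, 85.4, 80.7, 82.8 and 85.1% of genes in brain, heart, kidney and liver differed by less than 2-fold between the 2 libraries, with SDs of 0.91, 0.94, 0.92 and 0.84 log2 units. With 1 library of each kind per organ, none of these per-organ values has a replicate check.

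**Figure D1:**
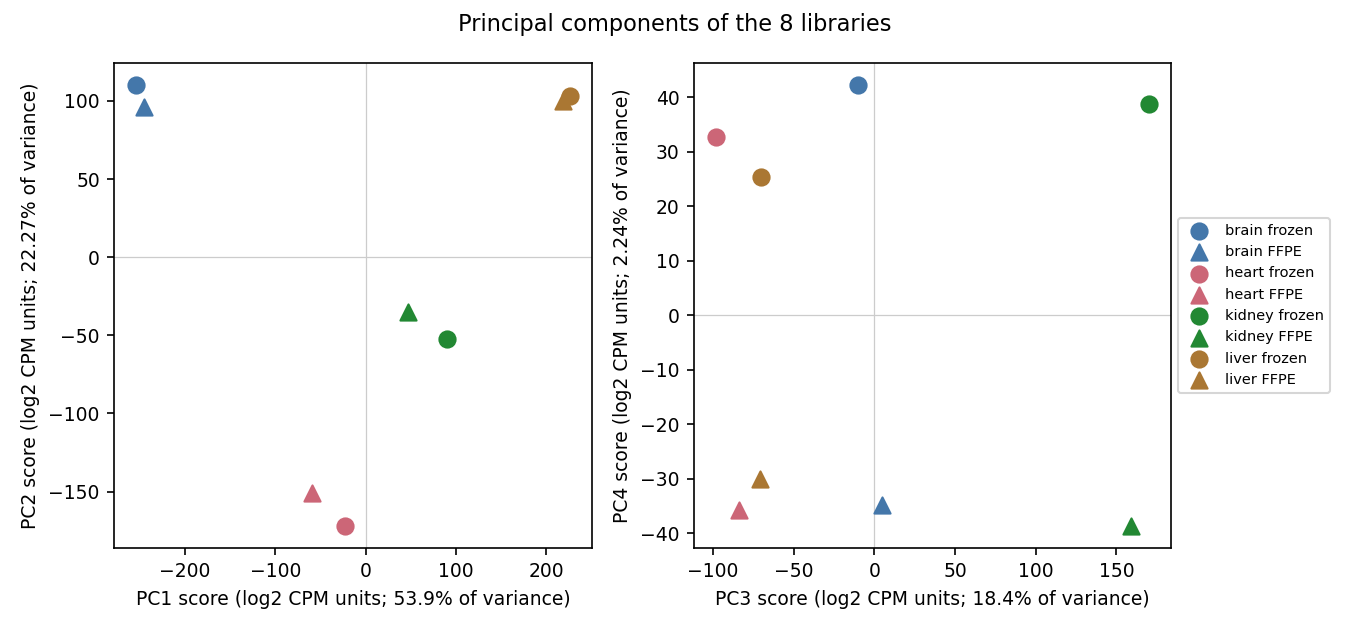
Scores of the 8 libraries on principal components 1 to 4 of the log2 CPM values (left, components 1 and 2; right, 3 and 4; circles, frozen; triangles, FFPE; colour, organ). Frozen and FFPE libraries of an organ lie together on the first 3 components, and component 4, with 2.24% of the variance, places all 4 frozen libraries above 0 and all 4 FFPE libraries below 0.

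Genes enriched in 1 organ were largely shared by the 2 preparations. Organ-enriched genes, those above 1 CPM and at least 8-fold above the highest of the other 3 organs, were picked separately in frozen and in FFPE libraries. Of 2854 organ-enriched genes in frozen tissue, 2387 were enriched in the same organ in FFPE tissue, a share of 83.6% (95% Wilson interval 82.2 to 84.9). Lists drawn independently would have shared 175.5 genes. The share was 82.5% of 1605 genes in brain, 83.4% of 307 in heart, 81.9% of 409 in kidney and 88.6% of 533 in liver. Only 1 frozen organ-enriched gene, from the liver set, stood in the FFPE set of another organ.

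Brain was marked by synaptic and neuronal genes in both preparations. The receptor genes Gabrb2 (log2 difference from the mean of the other 3 organs 11.10 ± 0.92 SE), Grm5 (10.78 ± 0.96) and Gria2 (10.64 ± 0.54) were among them. They encode a GABA receptor subunit, a metabotropic glutamate receptor and a subunit of an ionotropic glutamate receptor. Snap25, a protein of vesicle fusion, was higher by 10.87 ± 0.80 and Rab3c, a vesicle GTPase, by 10.78 ± 0.94. All 20 pan-neuronal markers, 16 of 16 oligodendrocyte and myelin markers, 16 of 16 GABAergic, 13 of 14 glutamatergic and 12 of 14 astrocyte markers were higher in brain, with list medians of 8.48, 7.75, 7.13, 8.27 and 4.65. Mobp, a myelin protein, lay 10.16 above the other organs and Mlc1, an astrocyte membrane protein, 9.44. Oligodendrocyte precursor markers (8 of 9 higher, median 5.92), cerebellar neuron markers (7 of 9, 7.69) and cilia and ependymal genes (7 of 7, 4.55) were higher as well. These values average the frozen and the FFPE library, which were unlike for the cerebellar list (median FFPE minus frozen difference in brain 0.90). Its members Gabra6 and Pcp2, chosen after their values were seen, had 0 reads in frozen brain and 742 and 98 in FFPE brain. Of the 16 macrophage and microglia markers 3 were higher and 6 lower, and of 10 choroid plexus markers 2 were higher and 3 lower, so neither list was called (limma's camera, adjusted p = 0.356 and 0.910).

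Limma's camera called the 8 brain lists with its preset correlation of 0.01. The calls were lost when the correlation was estimated from the 8 libraries (limma's camera, adjusted p = 0.149 to 0.247 with an estimated correlation). That form rests on 3 residual degrees of freedom, so the loss does not show that members varied together. Adjusted over the list alone, these 8 lists had as many higher members as over all genes. In brain against the other organs limma called 10498 genes at adjusted p under 0.05, of which 5495 were higher and 5003 lower, a balance that depended on scaling and turned to 4811 and 6427 under quantile normalization and to 4728 and 5935 after median centring. The 6 genes named first had limma adjusted p from 1.49e-06 to 1.99e-05.

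Heart was marked by the contractile apparatus. Mb (myoglobin, the muscle oxygen store) was higher than in the other organs by 13.89 ± 0.72 log2 units, Myl2 and Myl3 (ventricular myosin light chains) by 13.34 ± 0.76 and 13.03 ± 0.81, Myh6 (the alpha myosin heavy chain) by 13.21 ± 0.74, Actc1 (cardiac actin) by 12.94 ± 0.95 and Xirp2 (an actin-binding protein of intercalated discs) by 12.51 ± 1.05. All 22 sarcomere and calcium-handling genes (median 11.06) and all 18 ion channel and conduction genes (4.85) were higher. Nuclear genes of the respiratory chain and ATP synthase were higher in 78 of 81 cases (median 1.79), led by the muscle isoforms Cox6a2 (10.57) and Cox8b (10.41), and fatty acid oxidation genes in 17 of 20 (1.98), with Ehhadh, a peroxisomal enzyme, lower by −2.84. Endothelial (17 of 17, median 2.29), fibroblast and matrix (16 of 17, 3.01), smooth muscle and pericyte (11 of 12, 2.77), skeletal muscle (5 of 8, 4.56) and adipocyte markers (6 of 9, 1.56) were also higher in heart. Atrial markers were not called (3 of 7 higher, 1 lower; limma's camera, adjusted p = 0.114), with Nppa, the atrial natriuretic peptide gene, at 10.60. Of these organ lists the ventricle also expresses several genes counted as skeletal muscle markers, such as Ckm (12.18) and Acta1 (8.14).

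With an estimated correlation no heart list was called (limma's camera, adjusted p = 0.0731 to 0.324 with an estimated correlation for the 9 lists called above). In total limma called 7944 genes in heart, 3402 higher and 4542 lower, and this balance turned as well, to 4215 and 3921 under quantile normalization and to 4016 and 3655 after median centring. The 6 genes named had limma adjusted p from 2.44e-06 to 2.72e-05. Adjusted over the list alone, 79 respiratory chain members and 6 skeletal muscle markers were higher, and the other heart lists gave the numbers above.

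Kidney was marked by transport genes of the nephron. Kap, an androgen-regulated proximal tubule transcript, was higher by 14.45 ± 0.93 log2 units, Slc34a1, the sodium phosphate cotransporter, by 12.86 ± 0.96, Umod (uromodulin of the thick ascending limb) by 12.78 ± 1.21, Slc7a13, an amino acid transporter, by 12.75 ± 0.64, Acsm2, a medium-chain acyl-CoA synthetase, by 12.33 ± 0.57 and Cltrn (collectrin, which regulates amino acid transport) by 12.18 ± 0.61. All 21 proximal tubule (median 10.37), 16 loop of Henle and distal tubule (6.95) and 15 collecting duct markers (7.82) were higher. The collecting duct median was 7.30 when 2 genes without reads in the other organs were set at their bound of 3 reads per library. Podocyte markers were higher in 9 of 13 cases (median 1.21), among them Nphs1 (6.58), a slit diaphragm gene. Endothelial (7 of 17 higher, 2 lower), adrenal (0 of 5 higher, 2 lower), fatty acid oxidation (9 of 20 higher, 5 lower) and adipocyte markers (1 of 9 higher, 2 lower) were not called (limma's camera, adjusted p = 0.188, 0.139, 0.365 and 0.318).

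The 4 called kidney lists lost their calls with an estimated correlation (limma's camera, adjusted p = 0.113 to 0.145 with an estimated correlation). For kidney limma called 6369 genes, 3216 higher and 3153 lower (2940 and 4110 with log2(CPM + 5), 3493 and 3637 under quantile normalization, 3095 and 3333 after median centring), and the 6 genes named had limma adjusted p from 5.84e-06 to 8.65e-05. The count fell to 3028 without the frozen kidney library and to 4192 without the FFPE kidney library. Adjusted over the list alone, 10 fatty acid oxidation genes were higher and 6 lower, and the other kidney lists kept their numbers.

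Liver was marked by secreted plasma proteins and amino acid and drug metabolism. Serpina1e, a protease inhibitor, was higher by 14.96 ± 0.84 log2 units, Tat, which starts tyrosine breakdown, by 14.46 ± 1.00, Alb (albumin) by 14.42 ± 0.90, Plg (plasminogen) by 14.33 ± 0.90, Cyp3a11, a drug-metabolising cytochrome P450, by 14.30 ± 0.96 and Serpina3k by 14.09 ± 0.93. All members of 7 lists were higher, namely 26 genes of hepatocyte secreted proteins (median 11.78), 25 complement and coagulation factors (9.74), 22 bile acid and cytochrome P450 genes (11.66), 23 urea cycle and amino acid genes (9.19), 22 major urinary proteins (9.23), 18 cholesterol synthesis genes (3.34) and 14 male-biased liver genes (8.92). Gluconeogenesis genes were higher in 9 of 10 cases (median 5.70). With genes lacking reads in the other organs at their bound, the medians were 8.44 for the major urinary proteins, 10 of which had no such reads, and 11.46 for the bile acid list. Macrophage markers (8 of 16 higher, 4 lower) and female-biased liver genes (4 of 6 higher) missed the threshold (limma's camera, adjusted p = 0.0661 and 0.111), although Clec4f, a Kupffer cell lectin, lay 9.92 above the other organs. Serpina1e, the major urinary proteins and several cytochrome P450 genes have near-identical copies, so reads can be split among them and single values are uncertain.

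None of the 8 called liver lists was called with an estimated correlation (limma's camera, adjusted p = 0.0632 to 0.159 with an estimated correlation). In liver limma called 9888 genes, 4321 higher and 5567 lower, with limma adjusted p from 1.72e-06 to 5.22e-06 for the 6 genes named. Adjusted over the list alone, 10 macrophage markers were higher, and the other liver lists kept their numbers.

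Messenger RNAs for ribosomal proteins and for the respiratory chain stood at lower log2 CPM in FFPE than in frozen libraries in every organ. Of 84 cytoplasmic ribosomal protein genes 54 fell, with a median log2 fold change of −0.76, a 1.70-fold decrease. Rps10 (−1.37 ± 0.12 SE), Rps14 (−1.31 ± 0.13), Rps21 (−1.24 ± 0.11) and Rps2 (−1.24 ± 0.15), proteins of the small ribosomal subunit, had the largest changes. Of 81 genes listed as nuclear-encoded subunits of oxidative phosphorylation 55 fell (median −0.75). The list was drawn by symbol and took in the pseudogenes Atp5c1-ps and Uqcrh-ps1, which were not called. Among the 55 were Cox7c (−1.33 ± 0.17) of cytochrome oxidase and Atp5g2 (−1.28 ± 0.19), Atp5l (−1.22 ± 0.21) and Atp5k (−1.17 ± 0.20) of ATP synthase. The list medians in brain, heart, kidney and liver were −0.75, −0.89, −0.58 and −0.73 for ribosomal proteins and −0.59, −0.94, −0.87 and −0.64 for oxidative phosphorylation, each at percentile 0 among the medians of 10000 random gene lists of the same size and expression. The median of all tested genes lay at −0.01, 0.07, 0.06 and −0.04 in the same organs. Without the authors' scaling factors, as a share of all reads, ribosomal protein genes held 0.381, 0.261, 0.319 and 0.396% in frozen and 0.258, 0.236, 0.330 and 0.294% in FFPE tissue, so the direction flips in kidney on that scale, on which rRNA counts in the total. Members of both lists encode short transcripts, with a median length of 743 nt against 2796 nt in other protein-coding genes, and with trends in length and GC content removed 16 of 81 ribosomal and 15 of 79 oxidative phosphorylation genes stayed called as lower, at medians of −0.34 and −0.37. Many ribosomal protein genes have pseudogene copies that can share reads. Both lists were called as lower by limma's camera at adjusted p = 1.12e-51 and 2.92e-48, and both calls were lost with an estimated correlation (adjusted p = 0.198 with an estimated correlation for each).

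Camera called further lists as lower in FFPE, and none of these calls held with an estimated correlation. Mitochondrial ribosomal proteins fell in 9 of 78 cases (median −0.52; Mrpl20, −1.18 ± 0.15), replication-dependent histones, whose mRNAs end in a stem-loop without a poly(A) tail, in 6 of 31 (−0.74; H1f4, −1.20 ± 0.14), fatty acid oxidation genes in 6 of 20 (−0.51; Etfa, −0.75 ± 0.12, and Echs1, −0.74 ± 0.10) and housekeeping genes in 5 of 16 (−0.45; Gapdh, the glycolytic enzyme, −0.95 ± 0.18, and Pgk1, −0.75 ± 0.10). After trends with transcript length and GC content were removed, 0 of 78 mitochondrial ribosomal genes were called (smallest limma adjusted p = 0.0554). Their median change was then −0.32, and the median SE went from 0.17 to 0.14. The same removal took the medians to −0.39 for histones, −0.40 for fatty acid oxidation, −0.40 for housekeeping genes and −0.17 for the unfolded protein list named below. These 4 lists had adjusted p = 0.198 with an estimated correlation in limma's camera. Of 19 heat shock chaperone genes 3 fell (median −0.20), including Hspe1 (−0.67 ± 0.11) and Hsp90aa1 (−0.62 ± 0.12). Lyz2, a lysozyme of myeloid cells, fell by 1.30 ± 0.24 as the single called gene of 14 leukocyte markers (median −0.46), and C1qa, a complement gene of macrophages and microglia, by 1.08 ± 0.17 as the single called gene of 16 macrophage markers (−0.40). Male-biased liver genes had a median of −0.54, with Slco1a1, Cyp2d9 and Gstp1 (−1.03 ± 0.13) called among 14. Camera also called, as lower, stress response genes of unfolded protein (1 of 15 fell; Hyou1, −0.52 ± 0.10), gluconeogenesis (1 of 10; Pcx, −0.64 ± 0.12), hepatocyte secreted proteins (0 of 26) and cholesterol synthesis (0 of 18), with medians of −0.34, −0.17, −0.39 and −0.10. With an estimated correlation none of the 8 lists from the chaperones on was called (limma's camera, adjusted p = 0.30 to 0.626 with an estimated correlation). The hepatocyte list's median was −2.22 in brain and between −0.37 and 0.13 in the other organs.

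Some nuclear and clock transcripts rose in FFPE, while the calls of both lists were lost with an estimated correlation (limma's camera, adjusted p = 0.403 and 0.239 with an estimated correlation). Among 18 nuclear long non-coding RNAs, 2 rose (list median 0.71), namely Kcnq1ot1 (1.14 ± 0.15), which silences an imprinted cluster, and Ftx (0.84 ± 0.16), a gene next to Xist. Of 18 core circadian clock genes 3 rose (median 0.26), the period genes Per1 (1.08 ± 0.13), Per2 (1.35 ± 0.21) and Per3 (1.17 ± 0.26). Of 14 glucocorticoid and fasting response genes 5 rose (median 0.60), among them Zbtb16 (1.30 ± 0.19), Cdkn1a (1.15 ± 0.20) and Sgk1 (0.96 ± 0.20), and Per1 belongs to this list too. Transcripts of the mitochondrial genome had a median of 0.65, with 1 of 13 called, ATP6 (1.70 ± 0.18), a subunit of ATP synthase. Small non-coding RNA genes went both ways, with 21 of 145 rising and 7 falling (median 0.30), and their organ medians were 0.75 in brain and −0.02, 0.08 and −0.05 in heart, kidney and liver. Camera called 7 more lists as higher in which no single gene passed, at medians of 0.51 for immediate early genes, 0.78 for glutamatergic, 0.63 for pan-neuronal and 0.90 for cerebellar neuron markers, 1.26 for skeletal muscle, 1.43 for female-biased liver and 1.56 for atrial markers. None of these 12 calls held with an estimated correlation (limma's camera, adjusted p = 0.239 to 0.667 with an estimated correlation). Of the lists without a called gene, the female-biased liver median was 4.03 in liver, the atrial median 4.95 in heart and the immediate early median 1.34 in brain. The pan-neuronal median was −0.08 in brain, the organ that expresses these genes, 1.28 in heart and 1.49 in kidney, where members had a median of 3.5 and 2 reads in frozen and 23 and 12 in FFPE tissue, and −0.48 in liver, the value of 0 reads against 0.

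**Figure D2:**
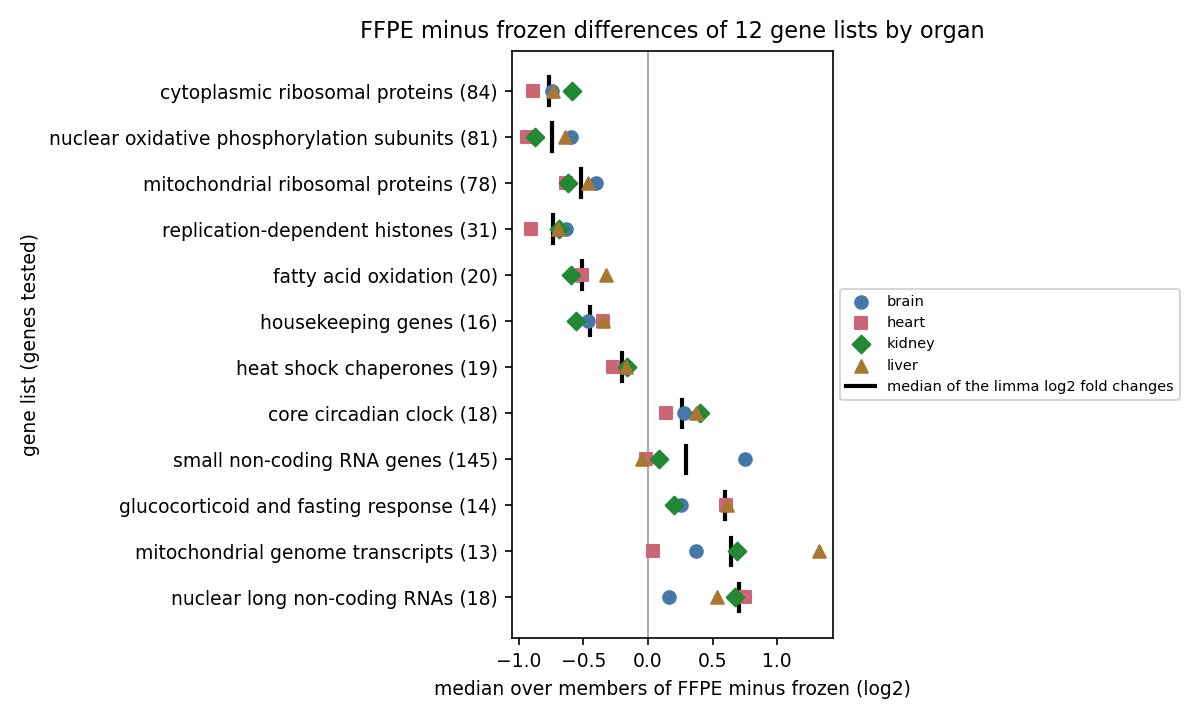
Median FFPE minus frozen difference (log2) over the members of 12 gene lists in each organ (coloured symbols, 1 pair of libraries each) and the median of the limma log2 fold changes (black bar; numbers of genes tested in parentheses). Ribosomal protein medians lie between −0.89 and −0.58 and oxidative phosphorylation medians between −0.94 and −0.59, while those of small non-coding RNA genes lie on both sides of 0.

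The largest rises among single genes belonged to Xist and to small structural RNAs. Xist, the RNA that coats the inactive X chromosome, had a log2 fold change of 8.56 ± 1.78 with organ differences of 0.09 in brain, 8.91 in heart, 12.96 in kidney and 12.28 in liver (chromosome X, 103460373 to 103483233, mm10). Snora75 (3.35 ± 0.58), Snora30 (2.72 ± 0.42), Snora16a (2.23 ± 0.34) and AF357399 (2.74 ± 0.46) are small nucleolar RNAs, Scarna8 (2.76 ± 0.59) is a Cajal body RNA, Rnu5g (3.26 ± 0.55) and Rnu11 (2.55 ± 0.46) are spliceosomal RNAs and Mir3068 (2.56 ± 0.38) is a microRNA gene. These RNAs often lie inside other genes, and the strand setting of the read counting is not given in the sources used here, so reads of a host gene can be counted for them. Nptx1 (2.86 ± 0.55), a neuronal pentraxin, held 0 to 12 reads outside brain and differed by 2.34 in brain. Scube1 (2.30 ± 0.46), a secreted and membrane protein, and Igha (2.59 ± 0.51), the constant region of immunoglobulin A, completed the 12 genes.

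The largest falls were those of Lars2 and 18S rRNA. Lars2, which encodes the mitochondrial leucyl-tRNA synthetase and whose transcript carries a stretch that resembles rRNA, fell by 5.09 ± 0.89 (chromosome 9, 123366927 to 123462675), and Rn18s fell by 4.78 ± 0.80. In kidney the differences were −8.41 for Lars2 and −7.46 for Rn18s, in heart −2.45 and −1.99. Slco1a1 (−1.84 ± 0.32), a hepatic and renal transporter, Cyp2d9 (−1.71 ± 0.25), a male-biased cytochrome P450, and Ces1f (−1.55 ± 0.32), a carboxylesterase, had at most 7 reads in any brain or heart library. In kidney and liver their differences were −1.42 and −0.94, −1.66 and −1.39, and −1.46 and −0.69. Bdh2 (−1.45 ± 0.31), a dehydrogenase, H4c17 (−2.48 ± 0.47), a histone gene, Rnaset2a (−1.92 ± 0.39), a lysosomal ribonuclease with a near-identical copy, Ubb-ps (−1.49 ± 0.32), a ubiquitin pseudogene, Snord35b (−1.83 ± 0.39), Snord22 (−1.67 ± 0.22) and Mir682 (−1.49 ± 0.26) made up the 12.

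In all, limma called 535 of 15819 genes between FFPE and frozen tissue at adjusted p under 0.05, with 190 higher and 345 lower. The 24 genes named had limma adjusted p from 0.0141 (Snord22) to 0.0469 (Scarna8), and all 535 had the same sign in 4 of 4 organs, which 4661 of the 15819 tested genes had. At least 2-fold changes numbered 81 higher and 88 lower. Adjusted over the list alone, 77 ribosomal protein, 74 oxidative phosphorylation, 46 mitochondrial ribosomal, 17 fatty acid oxidation, 9 histone, 9 housekeeping, 8 chaperone, 3 leukocyte, 2 macrophage and 3 male-biased liver genes were lower. On the same basis 7 nuclear long non-coding RNAs, 4 clock genes, 6 glucocorticoid response genes, 4 mitochondrial transcripts and 31 small non-coding RNA genes were higher. Camera called 26 of 52 lists, 12 higher and 14 lower, and 0 with an estimated correlation. The count of 535 depended on single libraries, since limma called 349 genes without frozen heart, 2 without either brain library and 0 without any 1 of the kidney or liver libraries (2173 to 2789 genes at an unadjusted p under 0.05). It was 0 without the mean-variance trend in limma (2904 genes at an unadjusted p under 0.05), 219 with length and GC trends removed and 1407 with voom.

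The 26 lists that camera did not call included hypoxia response, interferon response, red blood cell, endothelial, fibroblast, smooth muscle, adipocyte, adrenal, choroid plexus, sex-linked, GABAergic, astrocyte, oligodendrocyte and oligodendrocyte precursor markers, cardiac sarcomere and ion channel genes, the 4 nephron segment lists, 4 liver function lists, cell proliferation and cilia genes (limma's camera, adjusted p = 0.0653 to 0.978). Single genes passed in some of them. Ttn (titin, 1.37 ± 0.24), Cacna1c (0.86 ± 0.19), Synpo (0.65 ± 0.13) and Vegfa (0.53 ± 0.12) rose, and Hbb-bs, a beta globin gene, fell by 0.92 ± 0.20. The hypoxia list had a median of 0.07 and a mean of 0.11 with camera's direction down, the fibroblast list −0.01 and 0.04 with direction down, the proximal tubule list 0.01 and −0.14 with direction down, and the bile acid list 0.05 and −0.02 with direction down. Quantile normalization turned the sign of the median of the proximal tubule, bile acid, interferon, oligodendrocyte and oligodendrocyte precursor lists.

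Sex-linked transcripts checked the origin of the libraries. Xist, expressed in female tissue, stood at log2 CPM 9.03 in frozen brain and at 9.12, 8.46, 9.45 and 10.70 in FFPE brain, heart, kidney and liver, whereas frozen heart, kidney and liver held 7, 1 and 3 Xist reads. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, found in male tissue, stood at 3.67 to 5.95 in frozen heart, kidney and liver and at 3.28 to 4.41 in the 4 FFPE libraries, with 0 to 1 read each in frozen brain. All 4 FFPE libraries held transcripts of both kinds above 1 CPM, and 0 frozen libraries did. How many animals gave each sample, and of which sex, is not given in the sources used here.

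**Figure D3:**
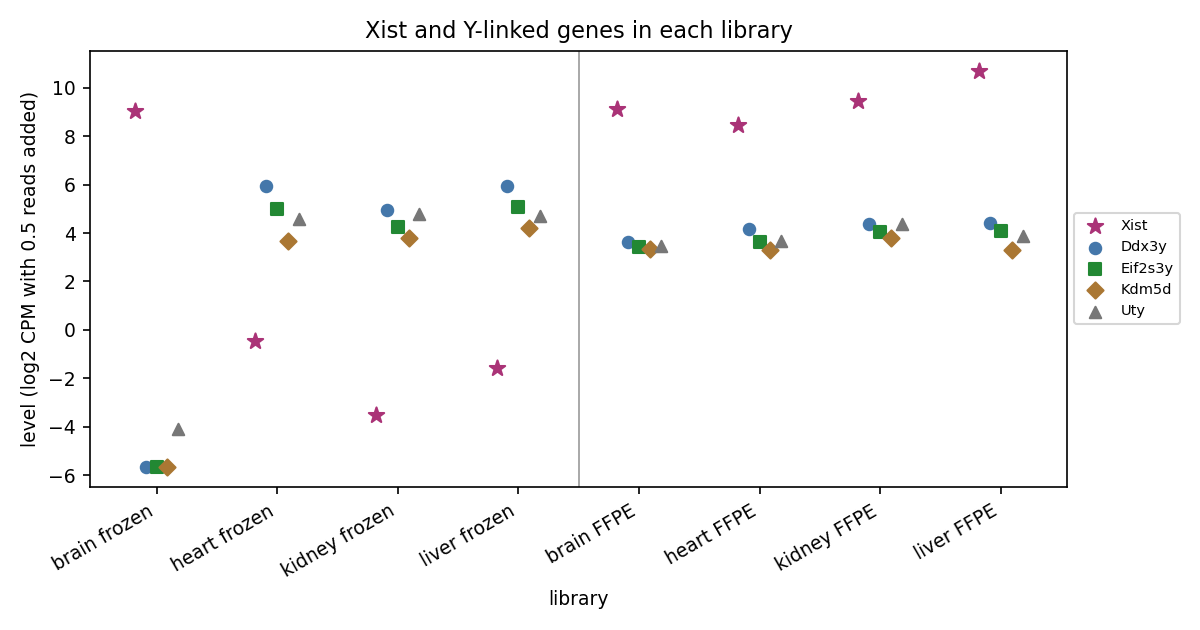
Levels (log2 CPM with 0.5 reads added) of Xist and 4 Y-linked genes in the 4 frozen (left) and 4 FFPE libraries (right). Frozen brain shows Xist at 9.03 and Y-linked genes at 0 to 1 read, the other frozen libraries the opposite, and each FFPE library both.

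FFPE libraries had reads in more genes than frozen libraries of the same organ. After each library was thinned to the same 4780823 reads outside rRNA, Lars2 and mitochondrial genes, the mean number of genes with reads was 17939.5 in frozen and 20204.1 in FFPE brain, 16080.0 and 17799.6 in heart, 16714.3 and 19225.4 in kidney and 15137.7 and 15925.9 in liver. Genes with reads in FFPE and none in frozen tissue of the same organ numbered 2950, 2623, 3573 and 1792 in brain, heart, kidney and liver, against 670, 581, 353 and 560 the other way. With 1 pair of libraries per organ these counts have no replicate check.

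**Figure D4:**
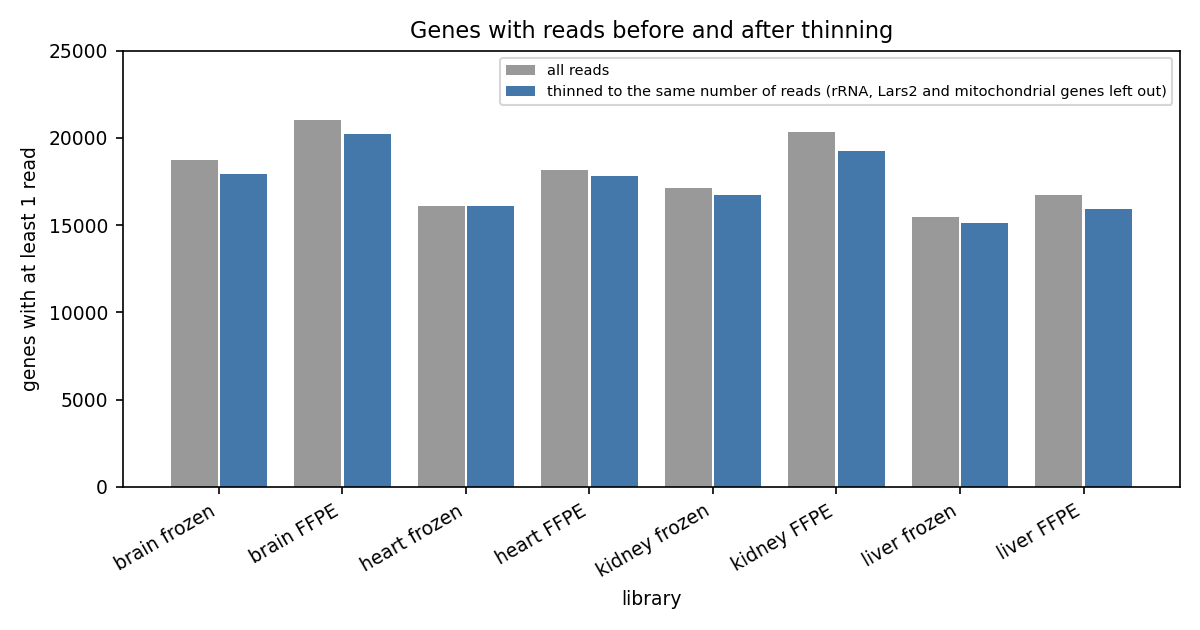
Number of genes with at least 1 read in each library, from all reads (grey) and after thinning to 4780823 reads outside rRNA, Lars2 and mitochondrial genes (blue, mean of 10 draws). In each organ the FFPE library has more genes than the frozen one in both counts, for example 20204.1 against 17939.5 in brain after thinning.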

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

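Of the tests in this part, those of library scaling, frozen brain reads, a mislabelled library, tissue of both sexes and genomic DNA (in the form given) were chosen after the results were seen, and those of length and GC content, pseudogenes, number of reads and reads from other organs before. The scaling test was changed more than once as well, from the difference to the median of all genes, which a library factor cannot change, to shares of all reads, which left scaling open, and then to other scalings. The genomic DNA test was changed more than once after results were seen. It compares read rates of olfactory receptor, vomeronasal receptor, and keratin-associated with defensin genes, and was first written for all members of these families. Members with reads in a frozen library were left out after Defb1 and Olfr1033 were seen to hold most reads in frozen libraries too. An earlier form argued against genomic DNA, with highest family rates 6.48, 9.63, 6.31 and 1.76 times the lowest per kb of coding length in brain, heart, kidney and liver (13.3, 19.7, 12.9 and 3.60 times per kb of exons). Another form, which left vomeronasal receptor genes out and added 200 nt per gene for reads over a gene's edge, narrowly missed the bound of 3, at 2.94, 2.64 and 2.86 in brain, heart and kidney with counting intervals still apart. The form below puts that family back, and its intervals from resampled genes were added after counting intervals alone had argued against genomic DNA.

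Ribosomal protein and respiratory chain mRNAs were lower in FFPE libraries of all 4 organs. Under quantile normalization, which took the called genes from 535 to 341, the medians were −0.72 (95% bootstrap interval −0.76 to −0.65) and −0.71 (−0.77 to −0.60). After median centring they were −0.75 and −0.73. Centring could hardly move them, because the median of all genes already lay at −0.01, 0.07, 0.06 and −0.04 in brain, heart, kidney and liver. Both scalings set the typical gene near 0, so they show a fall relative to other genes only. As a share of all reads, which include rRNA, ribosomal protein genes were 1.04 times as high in FFPE kidney. A fall on every scale is therefore not shown, and scaling stays open. The 100 members without a pseudogene named after them had a median log2 fold change of −0.75 (95% bootstrap interval −0.82 to −0.68). Names are an incomplete measure, since 93 of 158 members shared at least 10% of their 31-nt stretches with pseudogenes and only 65 had a named one. The 65 members that shared under 10%, a split not in the prediction set beforehand, had a median of −0.70 (−0.79 to −0.66). These values argue against reads shared with pseudogenes as the whole cause. Among the listed genes the pseudogenes Atp5c1-ps and Uqcrh-ps1 changed by 0.96 ± 0.32 and 0.17 ± 0.51, neither called. Atp5c1 changed by −0.66 ± 0.11 (called) and Uqcrh by −0.53 ± 0.15 (not called). A part played by shared reads is therefore not excluded. Transcript length and GC content could account for part of the fall, since other protein-coding genes of 500 to 1000 nt had a median of −0.36 and those over 4000 nt one of 0.22, and members lay −0.36 below genes matched on length, GC content and level, with an interval of −0.41 to −0.28 that reaches past the bound of −0.3 set beforehand. Whether length acts as the whole cause cannot be told apart from a separate fall of these genes on this test, although 16 of 81 ribosomal and 15 of 79 oxidative phosphorylation genes were still called as lower by limma after removal of the trend, at medians of −0.34 and −0.37, and fixation as named by the design stays open.

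Xist and Y-linked transcripts occurred together in each FFPE library. Reads carried over from the frozen brain library are argued against, because the Xist levels of FFPE heart, kidney and liver needed a share of brain RNA at least 65.1 times that allowed by the pan-neuronal markers. A single mislabelled library would not by itself put both kinds into 4 libraries, and 4 FFPE and 0 frozen libraries held both above 1 CPM. That count restates the pattern and could not have come out otherwise. A candidate explanation is tissue of both sexes in each FFPE sample, with which go the median of female-biased genes in FFPE liver, 4.03 above frozen liver, that of male-biased genes, −1.18, and that of Y-linked genes in heart, kidney and liver, −0.88. In heart, kidney and liver Xist had at most 7 reads in frozen and at least 4652 in FFPE libraries. Y-linked genes had at most 1 read each in frozen brain and 181 to 224 in FFPE brain. On these values the frozen and FFPE libraries of an organ did not hold RNA of the same animals only. Preservation and animals therefore cannot be told apart in any of the 4 pairs. Without sex-linked and sex-biased genes limma called 549 genes, which leaves other differences between animals in place.

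More genes had reads in FFPE libraries, and olfactory receptor genes, which lie outside the tested genes for the most part, had reads in 259, 91, 174 and 27 of 1126 members in FFPE brain, heart, kidney and liver against 25, 8, 11 and 8 in frozen tissue. The number of reads is argued against, because after thinning the FFPE library still had more genes in 4 of 4 organs. Genes above 1 CPM in another organ's frozen library are argued against as the main source. They made up at most 39.0% (liver) of the genes seen only in FFPE tissue of an organ. No share over all genes was set beside this. Tissue scarce in the frozen libraries could not count here, since frozen brain held 0 reads of Gabra6 and frozen heart 0 of Myl7. Reads from such tissue are therefore not excluded. Genomic DNA may be a source and stays open, because the kinds of interval given below disagreed. Rates were taken over members with a coding length and without reads in any frozen library. These were 86 of 98 keratin-associated and defensin genes and 1076 of 1126 olfactory receptor genes. Per kb of 50-mer positions unique to a gene, keratin-associated and defensin genes had 4.96, 7.37 and 4.83 times the reads of vomeronasal receptor genes in FFPE brain, heart and kidney. In heart this was 13 reads in 5 genes against 19 reads in 13 genes. Such positions were 55.6% of the vomeronasal and 83.8% of the olfactory receptor positions. Counting intervals were apart in these 3 libraries under all 6 length models, but intervals from resampled genes in 2 of 4. Olfactory receptor genes had 1.19, 1.97, 1.19 and 0.98 times the vomeronasal rate in brain, heart, kidney and liver. No biological explanation was tested.

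In 9 of 54 sets of 4 organ differences 1 organ stood far from the other 3, where chance gives about 1 in 20 for independent sets. The sets were named genes picked for the same sign in all organs, called lists and 4 Y-linked genes. They are not independent draws, so no excess over chance is read from the 9. Among the 9 were Ddx3y (9.30), Eif2s3y (9.06), Kdm5d (8.998) and Uty (7.53), each with brain apart. These 4 repeat a single fact, the near absence of Y-linked reads in frozen brain. Frozen brain had 0 reads of the first 3, so FFPE brain was at least 105-fold, 88.7-fold and 85.0-fold higher, and 1 read of Uty, for a ratio of 277 (counting interval 49.2 to 11012). Female-biased liver genes stood apart in liver (4.03), AF357399 in heart (0.68), Rnaset2a in kidney (−3.22) and small non-coding RNA genes in brain (0.75). Heat shock chaperones stood apart in heart by a small distance (−0.27, against −0.16, −0.17 and −0.17 in brain, kidney and liver).

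Some differences had opposite signs in different organs, which was not tested, since each organ has 1 pair of libraries. Ddx3y and Eif2s3y were lower in FFPE than in frozen heart by −1.80 and −1.35, opposite to brain. Proximal tubule markers had a median of 1.22 in heart, where 14 of 21 members had at most 4 reads in both libraries, so that sign rests on genes at the floor, and one of −2.06 in liver, where 8 of 21 did and the median number of reads was 11 in frozen and 2 in FFPE tissue.

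For the number of genes that differ between FFPE and frozen tissue, 1 of the 8 splits that part every organ's pair, the real one, called as many genes. These 8 splits are too few for a share under 0.05, with 535 genes in the real split and 0 as the highest of the others (limma, up to 882 genes at an unadjusted p under 0.05).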

How the results depend on the processing

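Removal of the length and GC trend, protein-coding genes only, removal of sex-linked genes and of the brain pair were chosen after seeing the data. Of 104 values of the comparisons under alternatives 81 stayed within the limits set and 23 moved. The balance of higher and lower genes turned in brain (5495 and 5003 to 4811 and 6427 under quantile normalization, 4728 and 5935 after centring and 5424 and 5434 with log2(CPM + 5)), in heart (3402 and 4542 to 4215 and 3921 and to 4016 and 3655 under the first and second of these) and in kidney (3216 and 3153 to 3493 and 3637, 3095 and 3333, and 2940 and 4110). The 535 genes between FFPE and frozen tissue became 341 under quantile normalization (335 shared), 325 with log2(CPM + 5) (315 shared), 1407 with limma's voom (528 shared), 169 with a 2-fold minimum, 219 with the length and GC trend removed (131 shared, against 437 for the same protein-coding genes without removal), and 0 without the trend in limma's variance (2904 genes at an unadjusted p under 0.05). Without the organ term, that is without the pairing by organ (no replicate block), limma called 0 genes (209 at an unadjusted p under 0.05), since differences between organs then enter the spread. The counts were 453 without a filter, 619 with the stricter one, 506 after centring, 618 with robust variance and 549 without sex-linked and sex-biased genes. Leaving out 1 library gave 0 to 397 genes, with 0 for each kidney or liver library, 2 for each brain library or the brain pair, 349 without frozen heart and 397 without FFPE heart, on fewer residual degrees of freedom. For kidney against the other organs the range was 3028 to 6489, and the other organ counts stayed within 1.5-fold, where the organ's lone library is assumed to vary like the others. Of 24 named FFPE genes 14 stayed called under quantile normalization, 23 after centring and 0 without the variance trend, and 21 of 21 under the stricter filter; in 288 of 288 cases named organ genes stayed called. Quantile normalization moved the median over all genes from 0.05 to −0.24 for brain and from −0.19 to 0.02 for heart, and centring to −0.20 and −0.01. Of 26 called FFPE lists and 29 called organ lists, camera with an estimated correlation, on 3 residual degrees of freedom, called 0 and 0. Limma's fry called 7 FFPE lists. Fry called the core circadian clock as higher (limma's fry, adjusted p = 0.00693). As lower it called cytoplasmic and mitochondrial ribosomal proteins, oxidative phosphorylation, histones, fatty acid oxidation and housekeeping genes (limma's fry, adjusted p = 0.0147 to 0.0179). Complement and coagulation factors were called as lower under quantile normalization (limma's camera, adjusted p = 0.0253), and 6 called lists lost their call there, namely heat shock chaperones, skeletal muscle, female-biased liver and cerebellar neuron markers (adjusted p = 0.0603 each), gluconeogenesis (0.0820) and pan-neuronal markers (0.131). Organ-enriched genes were shared at 71.2% with a 32-fold rule and 85.6% after quantile normalization, and the lowest correlation of an organ's 2 libraries was 0.966 by Spearman against 0.950 by Pearson. Where no reason is given, the cause was not tested. At 1 library per group, depth limits genes with few reads, so that genes absent from a library are not detectable there at 3 reads, 0.119 to 0.292 CPM.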

Other observations

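All genes in this part were chosen after their values were seen, each comparison rests on 1 pair of libraries without a replicate, and the intervals of ratios cover counting error only. FFPE heart held transcripts of atrial muscle that were scarce in frozen heart. Myl7, an atrial myosin light chain, had 1590 reads against 0 (at least 412-fold higher), Bmp10, an atrial growth factor, 706 against 0 (at least 183-fold) and Sln, the atrial regulator of the calcium pump, 536 against 0 (at least 139-fold). Myl4 was 305-fold higher (130 to 940) and Nppa had 7173 reads against 180. In FFPE brain, markers of the cerebellum stood out, with Gabra6 of granule cells at 742 reads against 0 (at least 348-fold) and Pcp2 of Purkinje cells at 98 against 0 (at least 46.0-fold). Slc17a7, the vesicular glutamate transporter of cortical and cerebellar neurons, was 30.8-fold higher (25.8 to 37.0), and Ttr, abundant in choroid plexus, 39.6-fold (28.9 to 55.8). FFPE kidney held the brown fat transcripts Ucp1 (144 reads against 0, at least 37.2-fold) and Cidea (77 against 0, at least 19.9-fold), the fat hormone gene Adipoq (73 against 1, 56.5-fold, 9.83 to 2263) and Dbh of adrenal medulla and sympathetic nerve (27 against 0, at least 6.97-fold).

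In FFPE liver, female-biased genes were present that frozen liver held at few or no reads. Cyp2b9 had 4205 reads against 1 (3018-fold, 541 to 119223) and Sult2a1, a sulfotransferase, 308 against 0 (at least 73.7-fold). The male-biased genes Hsd3b5 and Elovl3 were 4.05-fold (3.63 to 4.52) and 2.73-fold (2.61 to 2.85) higher in frozen liver. Low levels of other organs' transcripts occurred in both preparations. FFPE brain had 38 reads of the heart gene Myh6 against 5 in frozen brain (10.7-fold, 4.21 to 34.8), 48 of Mybpc3 against 1 (67.6-fold, 11.6 to 2725) and 11 of Tbx20 against 0 (at least 5.16-fold), and FFPE liver 44 of Myh6 against 3 (10.5-fold, 3.37 to 53.0). Frozen brain had 228 reads of Alb against 3 in FFPE brain (54.0-fold, 18.2 to 264) and 36 of Serpina3k against 0 (at least 8.52-fold). Frozen liver had 20 reads of Umod against 1 (27.9-fold, 4.46 to 1155), 37 of Kap against 4 (12.9-fold, 4.63 to 49.8) and 24 of Slc12a1, the salt transporter of the thick ascending limb, against 0 (at least 11.1-fold). In frozen brain Alb stood at 9.04 CPM, against 35200 CPM in frozen liver.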
